A study of Mus musculus with 15 samples.

How the data were processed

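Progenitor cells from C57BL/6 mouse bone marrow were enriched with CD117 beads and sorted by surface markers, and RNA libraries were made with Illumina TruSeq kits, per the labels' protocols. Both Csf1r gates were lineage-negative, CD117-positive, Sca1-negative, CD16/32-positive and CD34-positive. CMP were gated as intermediate for CD16/32 and CD34. Per the labels' protocols, GMP from mice with the inducible Gfi1 transgene were cultured overnight with doxycycline and then sorted for Venus. Whether the Venus-negative controls used here were cultured is not spelled out.

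The submitters' processing notes name Bowtie2, RSEM and the mouse build mm9, without versions. The deposited table holds log2 values for 23955 genes in 15 columns. The unit was read from the values: 2 to the power of each value, less 1, summed to between 999999 and 1000001 in each column used, in steps of 0.01 with a tolerance of 0.001. The deposited log2 values are therefore log2(TPM + 1). 9 columns had a name matching 1 sample's labels and no other. The other 6 columns matched no single sample and were used in no step, so the 6 samples with the induced Gfi1 transgene were not analysed here. The planned tests of Gfi1 induction, of its interaction with the Csf1r gate and of the transgene level were not run. The planned Csf1r test over 10 libraries became a test of 2 against 2 control libraries with no covariate. No gene coordinates are given, since no mm9 annotation was used here.

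Groups, tests, 20 gene lists and the rule for named genes were fixed before the data were examined. The Csf1r gates were compared with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean trend) on the deposited log2(TPM + 1) values, for genes with at least 1 TPM in at least 2 of the 4 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 differences are on the log2(TPM + 1) scale, which understates the change of genes with low values. Gene lists were tested with camera in limma, with a preset correlation of 0.01 and with the correlation estimated. The lists covered primary granule, secondary granule, monocyte, dendritic cell, stem cell, megakaryocyte and erythroid, eosinophil, basophil and mast cell, B lymphoid, T and NK, stromal, cell cycle, immediate early, interferon, glycolysis and hypoxia, integrated stress, cytokine response, Gfi1-repressed, myeloid transcription factor and ribosomal protein genes. A further list of mitochondrially encoded genes had no member in the table. Beside each list, fry in limma was also run. The fry test asks whether a list's own genes move on balance one way and compares them with no other genes. Its adjusted p was under 0.05 for stem cell, megakaryocyte and erythroid, and eosinophil, basophil and mast cell genes (0.0127 each). The same held by fry for Gfi1-repressed and ribosomal protein (0.0175 each), T and NK and myeloid transcription factor (0.0248 each), and secondary granule genes (0.0476). The T and NK list had 1 measured gene, Lck. The Gfi1-repressed list included Gfi1 itself and Csf1r, the gene of the sorted receptor. The ribosomal protein median log2 difference (-0.17) was close to that of all tested genes (-0.18).

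Single libraries were compared without a test. A gene counted as different when it reached 10 TPM in one library and differed by at least 2 on the log2 scale between LSK, CMP and GMP, or by at least 1 for the knockout-labelled libraries. List medians were placed among 10000 random lists of the same size matched on mean expression. List members entered with at least 1 TPM in one of the libraries compared, and the counts by the rule are over them. Differences between the Csf1r-sorted controls and the unsplit GMP library are given only among the other observations, because ribosomal RNA rows differed: Rn45s took 3.5 to 7.41% of the total in the 4 sorted controls and at most 0.125% in the other 5 libraries.

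Named genes were, for the Csf1r gates, the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 TPM in a gate, and up to 4 members of each list with the smallest p. For single libraries they were the 10 highest and 10 lowest differences and up to 4 members of each list with the largest difference. Gfi1, Irf8, Csf1r, Kit, Ly6a, Cd34, Fcgr3 and Fcgr2b were named for the Csf1r gates and for LSK, CMP and GMP, and only in part beside the knockout labels. Unnamed gene models were passed over. Flt3, Fos, Klf4, Bcl6, Ccnd2 and Amd2 in the Csf1r comparison, and H2-Ab1, S100a8 and Lcn2 beside the knockout labels, were named outside this rule, after their values were seen. Some genes were listed at 0 although every cell uses them (Eif3j1, for example), so an exact 0 can be a failed estimate. Such genes are given as listed at 0, with the value of each library.

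The limma step was tested on simulated data with 200 of 11795 genes changed in 20 runs of the Csf1r comparison. It recovered 11.5% of changes of 1 on the log2 scale, 87.8% of 2, 97.5% of 3 and 99.4% of 4, with 4.7% false calls. Alternatives tried were pseudocounts of 0.1 and 5, other minimum values, quantile normalization, median-of-ratios scaling, each library left out in turn and the control pairs (CAG and Rosa) as a block. Others were chosen after seeing the data: ribosomal and small RNA rows left out, median-of-ratios scaling of LSK, CMP and GMP, the direction of called genes in each control pair, and the CMP library as the reference for the knockout labels. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for the rest.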

Results

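Bulk RNA sequencing measured gene expression in progenitor cells sorted from mouse bone marrow. The series holds 15 samples, and 9 of them were analysed here. 4 were granulocyte-monocyte progenitors (GMP) split by surface Csf1r, the macrophage colony-stimulating factor receptor also called CD115. They formed 2 Csf1r-negative and 2 Csf1r-positive control libraries, negative for the Venus reporter of an inducible Gfi1 transgene. The other 5 were single libraries of lineage-negative Sca1-positive Kit-positive cells (LSK, the stem and multipotent progenitor fraction), common myeloid progenitors (CMP), unsplit GMP, GMP labelled Irf8-/- and GMP labelled Gfi1-/-. Values are TPM, each gene's share of a library's transcripts, scaled so that every library has the same total. TPM keep no sequencing depth, so the depth is unknown and no counting interval can be given. Between 10627 and 12196 genes had at least 1 TPM in a library. The 6 libraries with the induced Gfi1 transgene were not used here, so the effect of raising Gfi1 was not compared.

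The first comparison asked how GMP with surface Csf1r differ from GMP without it. Csf1r-positive GMP held more mRNA of 14 of 20 monocyte genes. Csf1r-negative GMP held more mRNA of all 11 eosinophil, basophil and mast cell genes, 16 of 18 megakaryocyte and erythroid genes, 12 of 17 stem cell genes, 7 of 13 secondary granule genes and 6 of 15 primary granule genes. These counts are of single genes, and no list as a whole held in camera with an estimated correlation (adjusted p = 0.45 or more with an estimated correlation). That estimate rests on 2 residual degrees of freedom and has little power, so a list that did not hold may still differ. Lyz2, the macrophage lysozyme, stood at 18740 ± 3039 TPM in Csf1r-positive and 757 ± 153 TPM in Csf1r-negative GMP (SD, n = 2 each), a log2 difference of 4.63 (SE 0.26, limma adjusted p = 0.00098). Its near-identical copy Lyz1 was at 2727 and 99.9 TPM on average, so how reads divide between the pair is uncertain. Gzmb, a granule serine protease, was at 0.18 TPM and listed at 0 in the Csf1r-positive libraries, and at 839 and 609 TPM in the Csf1r-negative ones (log2 difference -9.36, SE 0.23, limma adjusted p = 0.00015). Gfi1, the transcriptional repressor needed for neutrophil development, was at 13.1 ± 4.41 TPM in Csf1r-positive and 148 ± 0.856 TPM in Csf1r-negative GMP (SD, n = 2 each; log2 difference -3.44, limma adjusted p = 0.0017). Irf8, a transcription factor that directs monocyte and dendritic cell fate, was at 93 and 25.9 TPM on average (log2 difference 1.93, limma adjusted p = 0.03). This call was lost without Csf1r-positive replicate 1 (limma adjusted p = 0.0939), without Csf1r-positive replicate 2 (0.0761) and when every gene above 0 was tested (0.0585).

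**Figure D1:**
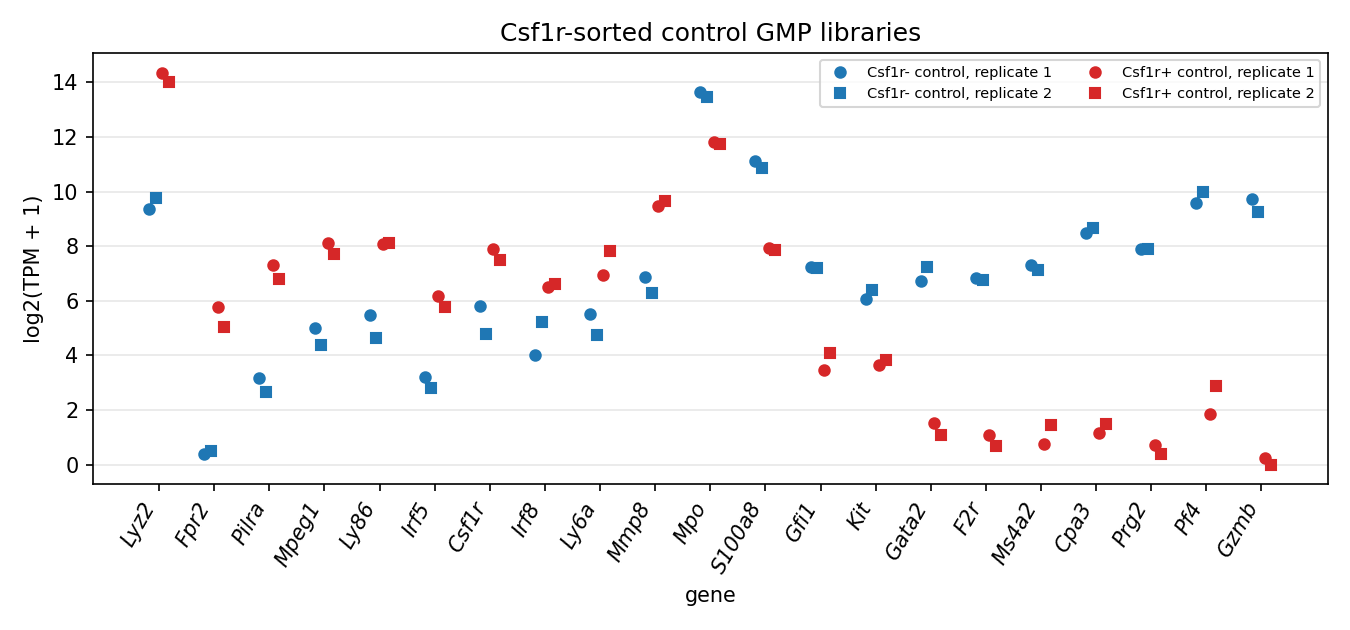
Expression of 21 named genes on the log2(TPM + 1) scale in the 4 Csf1r-sorted control libraries, with 1 point per library, blue for Csf1r-negative and red for Csf1r-positive GMP. Lyz2 lies near 18740 TPM in the Csf1r-positive libraries and near 757 TPM in the Csf1r-negative ones, and Gzmb lies at 839 and 609 TPM in the Csf1r-negative libraries.

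Of 11795 genes tested, 1596 differed at a Benjamini-Hochberg adjusted p under 0.05 in limma, 568 higher and 1028 lower in Csf1r-positive GMP, and 3840 had an unadjusted p under 0.05. The median log2 difference of all tested genes was -0.18, so the genes that fell lay partly on a general offset. With median-of-ratios scaling the split was 750 higher and 768 lower, and with quantile normalization it was 705 higher and 584 lower. All 1596 called genes had both Csf1r-positive libraries on the same side of both Csf1r-negative ones, as did 62.8% of the tested genes, where chance gives 33.3%. The number of calls was 741 without Csf1r-negative replicate 2, 518 without Csf1r-positive replicate 1 and 985 without Csf1r-positive replicate 2. Nothing in the labels says that replicates came from separate animals or cultures, so these p-values measure the spread between these samples, which may be technical. The replicates of each gate carry the different name stems CAG and Rosa, so any difference between these stems also enters this spread.

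Monocyte and macrophage genes rose in Csf1r-positive GMP, 14 of the 20 measured passing the test over all genes and 18 when adjusted over the list alone, with none falling. Without Csf1r-positive replicate 1, 8 passed. Among them, the extracellular matrix gene Fn1 went from 2.53 ± 0.311 to 39.7 ± 5.16 TPM and the pore-forming Mpeg1 from 25.4 ± 7.56 to 245 ± 48.1 TPM (SD, n = 2 each). Ly86, a partner of the Toll-like receptor family, was at 34.1 and 272 TPM on average, and Ms4a6c at 13.9 and 112 TPM. Csf1r itself, the gene of the sorted receptor, was at 40.6 ± 19.6 and 210 ± 42 TPM (SD, n = 2 each; log2 difference 2.41, limma adjusted p = 0.012, and 0.0508 without Csf1r-positive replicate 1). Dendritic cell and antigen presentation genes included 6 that rose, 1 that fell (Flt3) and 5 that did not pass, and 8 rose and 2 fell when adjusted over the list alone. Flt3 was not called when any 1 of the 4 libraries was left out. The invariant chain Cd74 was at 151 and 729 TPM, the MHC class II gene H2-Aa at 44.8 and 221 TPM and the protease inhibitor Cst3 at 348 and 1341 TPM in Csf1r-negative and Csf1r-positive GMP. The camera test with a preset correlation put the monocyte list (adjusted p = 1.7e-15) and the dendritic list (adjusted p = 0.00012) above the other genes. With an estimated correlation neither held (adjusted p = 0.45 with an estimated correlation for the monocyte list and adjusted p = 0.46 with an estimated correlation for the dendritic list).

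All 11 measured eosinophil, basophil and mast cell genes fell in Csf1r-positive GMP, also when adjusted over the list alone. Without Csf1r-negative replicate 1 or replicate 2, 4 of them met the minimum for the test, and all 4 fell. The mast cell carboxypeptidase Cpa3 was at 382 ± 33.6 against 1.51 ± 0.41 TPM, the eosinophil major basic protein gene Prg2 at 239 ± 0.806 against 0.49 ± 0.24 TPM, and the IgE receptor subunit Ms4a2 at 148 ± 11.4 against 1.23 ± 0.75 TPM in Csf1r-negative and Csf1r-positive GMP (SD, n = 2 each). Of the 18 megakaryocyte and erythroid genes, 16 fell and none rose, and 17 fell when adjusted over the list alone. Without Csf1r-negative replicate 1, 6 of the 9 that met the minimum fell, and without replicate 2, 8 of 9. The platelet chemokine Pf4 was at 886 ± 183 against 4.47 ± 2.66 TPM (SD, n = 2 each), Itga2b at 49.5 against 0.385 TPM on average, and Gata1 at 15.8 and 18.7 TPM in the Csf1r-negative libraries and listed at 0 in both Csf1r-positive ones. Of the 17 stem and multipotent progenitor genes, 12 fell, 1 rose (Ly6a) and 4 did not pass, and 13 fell and 1 rose when adjusted over the list alone. Without Csf1r-negative replicate 2, 7 of the 12 that met the minimum fell. Gata2 was at 128 against 1.52 TPM, Ctla2a at 84 against 6.2 TPM and Angpt1 at 36.8 against 0.385 TPM. Ly6a, which encodes Sca1, was higher in Csf1r-positive GMP (173 ± 71.1 against 35.5 ± 13.9 TPM, SD, n = 2 each, log2 difference 2.24), although both gates were sorted as Sca1-negative. Camera with a preset correlation called all 3 lists lower (adjusted p = 2.7e-12, 6e-12 and 1.9e-06), and none held with an estimated one (adjusted p = 0.45 with an estimated correlation for each).

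Many neutrophil genes fell in Csf1r-positive GMP, and Mmp8 and Hp rose. Of the 13 measured secondary granule and late neutrophil genes, 7 fell, 1 rose and 5 did not pass, and 9 fell and 2 rose when adjusted over the list alone. Without Csf1r-negative replicate 1, 4 of the 11 that met the minimum fell, and without Csf1r-positive replicate 1, 2 genes rose. Ngp was at 579 ± 28.9 against 7.65 ± 7 TPM and the alarmin S100a8 at 2041 ± 265 against 237 ± 10.4 TPM, whereas the collagenase Mmp8 rose from 96.6 ± 27.7 to 750 ± 65.3 TPM (SD, n = 2 each). Of the 15 primary granule genes, 6 fell, 1 rose and 8 did not pass, and 8 fell and 1 rose when adjusted over the list alone. Myeloperoxidase, Mpo, fell from 11991 ± 955 to 3523 ± 103 TPM and haptoglobin, Hp, rose from 227 ± 34.9 to 678 ± 22.6 TPM (SD, n = 2 each). When every gene above 0 was tested, 2 primary granule genes fell, and the Mpo call was lost (limma adjusted p = 0.0565). Camera with a preset correlation called the secondary (adjusted p = 0.0027) and primary (adjusted p = 0.025) granule lists lower, and with an estimated one neither held (adjusted p = 0.46 with an estimated correlation for both).

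Among myeloid transcription factors, 5 rose, 9 fell and 7 did not pass, and 7 rose and 9 fell when adjusted over the list alone. Without Csf1r-positive replicate 1, 2 rose. Irf5 was at 63.1 against 7.1 TPM, and Klf4, a monocyte regulator, at 49.2 against 6.82 TPM in Csf1r-positive and Csf1r-negative GMP. The Klf4 call was lost without Csf1r-positive replicate 1 (limma adjusted p = 0.0537). Myb, a factor of immature progenitors, was at 95.6 against 463 TPM. The other risers were Irf8, Cebpb (limma adjusted p = 0.0651 without Csf1r-positive replicate 1) and Id2. Of 11 genes described as repressed by Gfi1, 3 rose (Csf1r, Id2 and Irf8) and 6 fell, among them Pbx1 (5.99 against 52.5 TPM) and Meis1 (4.03 against 24.6 TPM), with 4 and 7 when adjusted over the list alone. This list holds Gfi1 itself, which was among those that fell, and Csf1r, the gene of the sorted receptor. Without Csf1r-positive replicate 1, 1 rose and 3 fell. Camera called neither the transcription factor list (adjusted p = 0.89, direction up, median 0.06, mean -0.39) nor the Gfi1-repressed list (adjusted p = 0.37, direction down). For the sort markers, Kit was at 12.3 TPM in Csf1r-positive and 74.4 TPM in Csf1r-negative GMP (log2 difference -2.49, limma adjusted p = 0.0024). The log2 differences of Cd34 (-0.27), Fcgr3 (0.34) and Fcgr2b (-0.50) did not pass.

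The largest rises also included the formyl peptide receptor Fpr2 (0.365 to 43 TPM), Pilra (6.72 to 135 TPM), Bst1 (1.98 to 45.5 TPM), Cd302 (2.21 to 52.2 TPM) and Pid1 (0.465 to 19.8 TPM). The largest falls included the thrombin receptor F2r (110 to 0.875 TPM) and the steroid-synthesis enzyme Cyp11a1 (273 to 4.5 TPM). Lyz1, Pira1, Pira7, Amd1 and Pisd-ps1 were also among them, but each has a near-identical copy, so their values are uncertain, as is that of Lyz2. Amd1 was listed at 0 in both Csf1r-negative libraries while its copy Amd2 was at 92.2 and 76.9 TPM there. Of 22 DNA replication and mitosis genes, 1 passed (Ccne1, 34.4 against 16.5 TPM in Csf1r-positive and Csf1r-negative GMP), and none when adjusted over the list alone. Camera put that list higher (adjusted p = 0.0029, and adjusted p = 0.45 with an estimated correlation), with a median log2 difference of 0.23, but not after quantile normalization (adjusted p = 0.364). The Ccne1 call was lost when every gene above 0 was tested (limma adjusted p = 0.0524), without Csf1r-negative replicate 1 (0.0863), without Csf1r-positive replicate 1 (0.0863) and without Csf1r-positive replicate 2 (0.0993). 4 immediate early genes rose (Fos, Zfp36, Klf2 and Klf6) and 1 fell (Egr1) of 12, with 8 and 1 when adjusted over the list alone (camera adjusted p = 0.00053, and adjusted p = 0.46 with an estimated correlation). Without Csf1r-positive replicate 1 the calls of Fos (limma adjusted p = 0.119), Klf6 (0.127) and Zfp36 (0.127) were lost. Without Csf1r-positive replicate 2 those of Fos (0.136), Egr1 (0.052), Klf2 (0.0742) and Zfp36 (0.0686) were lost. The Fos call was also lost without Csf1r-negative replicate 1 (0.079) and replicate 2 (0.186). When every gene above 0 was tested, Fos (0.09), Klf2 (0.0643), Klf6 (0.0632) and Zfp36 (0.0679) were lost, so no riser of this list held. 1 T and NK gene (Lck) and 1 stromal gene (Vcam1, 17.7 against 0.24 TPM in Csf1r-negative and Csf1r-positive GMP) fell, and no B lymphoid gene of 3 passed. The Lck call was lost after quantile normalization (limma adjusted p = 0.0734), without Csf1r-positive replicate 1 (0.0877) and without Csf1r-positive replicate 2 (0.0604). The interferon, glycolysis, integrated stress, cytokine response and ribosomal protein lists were not called by camera (adjusted p = 0.18, 0.34, 0.37, 0.54 and 0.85), with 2, 0, 1, 1 and 0 members rising and 0, 1, 0, 5 and 0 falling. These were Mx1 and Zbp1 of the interferon list, Pfkfb3 of the glycolysis list, Cebpb of the integrated stress list, and Bcl6 (higher), Pim2, Myc, Ccnd2, Il2ra and Csf2rb2 of the cytokine response list. Mx1, Zbp1, Pfkfb3, Csf2rb2 and Ccnd2 each lost the call under at least 4 alternatives. Bcl6 lost it without Csf1r-positive replicate 1 (limma adjusted p = 0.112), without Csf1r-positive replicate 2 (0.08) and when every gene above 0 was tested (0.0693). The integrated stress list had a median of -0.21 and a mean of 0.03. Of the cytokine response genes, 2 fell without Csf1r-negative replicate 2 and 3 when any other library was left out. Without Csf1r-positive replicate 1 the glycolysis list was called higher (camera adjusted p = 0.00387), and without Csf1r-positive replicate 2, 4 of its genes fell. Adjusted over the list alone, 2, 0, 1, 2 and 0 rose and 1, 0, 0, 5 and 0 fell. In the same order, the B lymphoid, T and NK, and stromal lists had adjusted p = 0.54, 0.21 and 0.54, and 1, 0 and 1 members rose and 0, 1 and 2 fell when adjusted over the list alone.

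The second comparison followed the step from LSK to CMP and GMP, with 1 library each, so differences have no replicate check and no test was run. Primary granule genes were far higher in CMP and GMP than in LSK, and many stem cell and interferon-stimulated genes were far lower. Neutrophil elastase, Elane, was at 130 TPM in LSK, 12185 TPM in CMP and 11777 TPM in GMP, and Ms4a3 at 26.4, 1476 and 1417 TPM. Dntt, the terminal transferase of lymphoid progenitors, was at 570, 0.49 and 0.13 TPM, the cytokine receptor Flt3 at 468, 5.11 and 5.39 TPM, and the thrombopoietin receptor Mpl at 150, 1.22 and 0.95 TPM. A gene counted as different when it reached 10 TPM in one library and the log2 difference was at least 2. By this rule 162 genes were higher and 644 lower in CMP than in LSK, and 184 were higher and 642 lower in GMP than in LSK. The median log2 differences of all genes at 10 TPM were -0.32 and -0.30, and median-of-ratios scaling gave 220 higher and 442 lower for CMP and 258 higher and 441 lower for GMP.

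From LSK to CMP, 14 of 15 primary granule genes were higher by the rule and none lower, a list median of 4.43 on the log2 scale. It lay at percentile 100 among 10000 random lists of the same size and expression, as did the secondary granule (median 1.32, 6 of 14 higher) and monocyte lists (median 1.21, 6 of 20 higher, among them Ly6c2, 68.6 to 3390 TPM, and F13a1, 7.63 to 285 TPM). Stem and multipotent genes were lower in 15 of 21 (median -3.30), with Hlf at 221 and 4.54 TPM, Mecom at 36.5 and 0.2 TPM and Mycn at 65.7 and 0.34 TPM. Interferon-stimulated genes were lower in 11 of 17 (median -2.83), with Rtp4 at 87.9 and 2.06 TPM and Oasl2 at 78.9 and 4.35 TPM. Dendritic cell genes were lower in 5 of 17 (median -1.68), B lymphoid genes in 3 of 9 (median -2.46) and megakaryocyte and erythroid genes in 5 of 17 (median -1.23), with Car2 at 611 and 20.1 TPM. These 5 lower lists lay at or below percentile 0.25. For the receptors that define the gates, Fcgr3 was at 15.5 TPM in LSK, 434 TPM in CMP and 444 TPM in GMP, and Cd34 at 1039, 260 and 244 TPM. Gfi1 was at 57.5, 139 and 157 TPM, Irf8 at 56.6, 198 and 205 TPM, and Csf1r at 14.8, 68.7 and 72.3 TPM. In the same order Kit was at 374, 139 and 145 TPM, Ly6a at 187, 95.3 and 107 TPM, and Fcgr2b at 16.2, 128 and 132 TPM.

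CMP and GMP differed at few genes. By the same rule 11 genes were higher and 1 lower in GMP. Of the higher ones, Reg3b (22.4 TPM) and Fabp2 (10.5 TPM) are genes of the intestine and were listed at 0 in CMP. The lower one, Eif3j1, was listed at 0 in GMP and shares reads with the near-identical Eif3j2. 8 of 15 secondary granule and late neutrophil genes were higher in GMP (list median 2.25, percentile 100), with Ltf at 12.6 and 192 TPM, Ngp at 85.3 and 1047 TPM, Camp at 133 and 1137 TPM and Lcn2 at 40.1 and 284 TPM in CMP and GMP. No gene of the primary granule, monocyte, stem cell, immediate early, or megakaryocyte and erythroid lists met the rule. The immediate early list had a median of -0.94 and the megakaryocyte and erythroid list one of -0.26, both at percentile 0, with Hspa1a at 95.4 and 26.5 TPM and Jun at 23.2 and 7.53 TPM, and Pf4 was at 23.6 and 9.19 TPM. Between 30 and 100 TPM, the interquartile range of the log2 difference was 0.13 between CMP and GMP. It was 0.42 and 0.44 between the replicate libraries of each Csf1r gate, whose names carry the different stems CAG and Rosa.

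**Figure D2:**
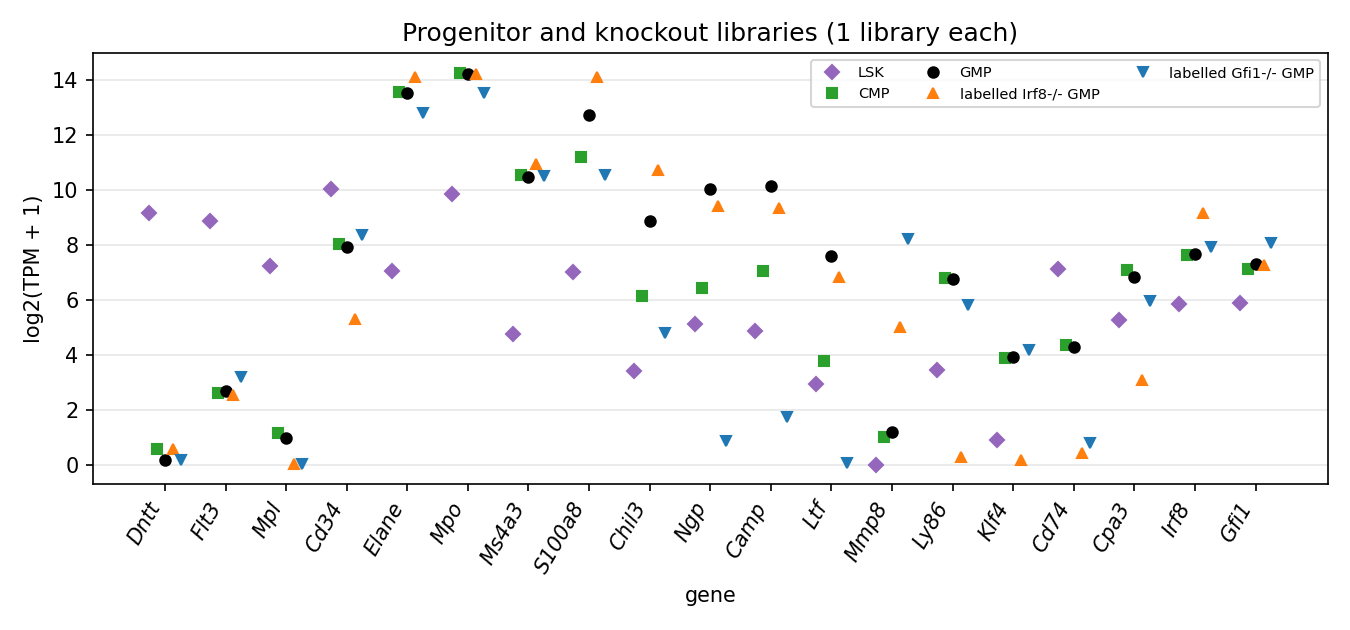
Expression of 19 genes on the log2(TPM + 1) scale in the LSK, CMP, GMP and knockout-labelled GMP libraries, with 1 library and 1 point each. CMP and GMP points nearly coincide except at S100a8, Chil3, Ngp, Camp and Ltf. The library labelled Gfi1-/- lies near 0 at Ngp, Camp and Ltf.

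The third comparison set GMP labelled Irf8-/- and Gfi1-/- beside the unlabelled GMP library, again with 1 library each. The GMP library, the reference for both, held mRNAs of more intestinal genes than any other library (Reg3b at 22.4 TPM). Whether material or reads of another sample entered the GMP library was not tested. The targeted genes came first, as a check of the labels. Irf8 was at 205 TPM in GMP, 568 TPM in the library labelled Irf8-/- and 241 TPM in the library labelled Gfi1-/-. Gfi1 was at 157, 153 and 267 TPM in the same order. In the other libraries Irf8 was at 56.6 TPM in LSK, 198 TPM in CMP, 15.1 and 36.6 TPM in Csf1r-negative and 89.7 and 96.2 TPM in Csf1r-positive GMP, and Gfi1 at 57.5, 139, 149, 148, 9.99 and 16.2 TPM. Each targeted mRNA was thus higher, not lower, in the library labelled as its knockout. The values are sums per gene, so reads from exons left in place cannot be separated, and every direction below rests on those labels. Xist was at 52 TPM in the library labelled Irf8-/- and at 0.29 TPM or less in the other 8, so this library also differed in sex.

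In the library labelled Irf8-/-, some monocyte and antigen presentation genes were nearly missing while several neutrophil genes were higher. Ly86 was at 106 TPM in GMP and 0.22 TPM in the library labelled Irf8-/-, Klf4 at 14 and 0.14 TPM, Cd74 at 18.5 and 0.36 TPM and Irf5 at 17.2 and 2.58 TPM. The dendritic cell list as a whole lay among the random lists (2 of 9 lower, median -0.43, percentile 55.7), and the MHC class II gene H2-Ab1 was at 19.3 and 22.8 TPM. Chil3, a chitinase-like protein of neutrophils, was at 464 and 1681 TPM, Mmp8 at 1.31 and 31 TPM and the chemokine receptor Ccr2 at 58.8 and 185 TPM. The largest rises also held thrombospondin, Thbs1 (0.58 to 80.7 TPM), Tmem178 (2.78 to 137 TPM), Saa3 (0.17 to 18 TPM) and Hopx (3.88 to 46.9 TPM). A gene counted as different at 10 TPM in one library and a log2 difference of at least 1. By this rule 85 genes were higher and 1354 lower, but the median log2 difference of all genes was -0.44, and median-of-ratios scaling gave 274 higher and 362 lower. Against that offset, eosinophil, basophil and mast cell genes stood out as low, 7 of 12 lower by the rule (median -1.58, percentile 0), with Cpa3 at 112 and 7.59 TPM. Megakaryocyte and erythroid genes had a median of -1.54 (4 of 15 lower and 1 higher, percentile 0) and stem cell genes one of -1.24 (5 of 12 lower, percentile 0.02), with Gata2 at 23.5 and 1.32 TPM and Angpt1 at 13.2 and 0.29 TPM. Interferon-stimulated genes had a median of 0.28 (percentile 100, 2 of 15 higher), with Rtp4 at 2.39 and 17.1 TPM. The monocyte list had a median of 0.39 (percentile 100) but a mean of -0.31, so its members went both ways. By the rule 3 of 18 were higher (Ccr2, F13a1 and the targeted gene Irf8 itself). Of the others, 4 were lower, among them Klf4, Ly86 and Zeb2. The secondary granule list (median -0.14, percentile 71.1) had 4 of 15 higher and 2 lower, and against the CMP library its median was 2.76 (percentile 100). Cd34 was at 244 and 38.6 TPM, although both populations were gated as CD34-positive.

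In the library labelled Gfi1-/-, some secondary granule genes were nearly missing, while others of that list were not. Ngp was at 1047 TPM in GMP and 0.81 TPM in the library labelled Gfi1-/-, Camp at 1137 and 2.3 TPM, Ltf at 192 and 0.04 TPM and Fcnb, of the primary granule list, at 431 and 17.7 TPM. Of 15 secondary granule genes, 10 were lower and 1, Mmp8, was higher (1.31 to 294 TPM), with a median of -3.32 (percentile 0). S100a8 was at 6724 and 1506 TPM and Lcn2 at 284 and 301 TPM. CMP held less of these mRNAs than GMP, and against the CMP library the median was -1.06 (percentile 0). Elane (11777 to 7059 TPM) and Mpo (19158 to 11661 TPM) differed less, and the primary granule median was -0.41 (percentile 0.02). Higher genes included Ifitm1 (43.3 to 742 TPM), Hopx (3.88 to 77.7 TPM), Maged1 (3.05 to 57.9 TPM), Cd302 (1.82 to 35.5 TPM), Bmx (3.68 to 39 TPM) and the homeobox gene Hoxa9 (12.4 to 41.7 TPM). Cytokine response genes had a median of 0.38 (percentile 99.97, 3 of 14 higher and 1 lower), with Pim1 at 30.4 and 154 TPM and Csf2rb2 at 4.9 and 25.4 TPM. Interferon-stimulated genes had a median of -1.15 (percentile 0, 2 of 15 lower), with Oas1a at 27.9 and 8.37 TPM. Of 9 dendritic cell genes, 3 were lower (median -0.31, percentile 49.5), with Cd74 at 18.5 and 0.72 TPM and H2-Aa at 11.3 and 0.65 TPM, whereas H2-Ab1 was at 19.3 and 20.1 TPM. Eosinophil, basophil and mast cell genes (median -0.87, 4 of 13 lower) and megakaryocyte and erythroid genes (median -0.86, 3 of 15 lower) lay at percentiles 0.03 and 0.27. Monocyte genes went both ways (3 of 19 higher and 2 lower, median -0.01, percentile 86.8), with Ctss at 29.1 and 128 TPM and Cx3cr1 at 11.7 and 1.59 TPM. Of 11 genes described as repressed by Gfi1, 1 was higher by the rule (Hoxa9) and 2 lower, and the median of -0.05 lay at percentile 87.1. These 11 include the targeted gene Gfi1 itself (157 and 267 TPM), which did not meet the rule. By the rule 127 genes were higher and 656 lower, with a median log2 difference of all genes of -0.22, and median-of-ratios scaling gave 227 higher and 298 lower. With a minimum of 20 TPM the total was 507.

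**Figure D3:**
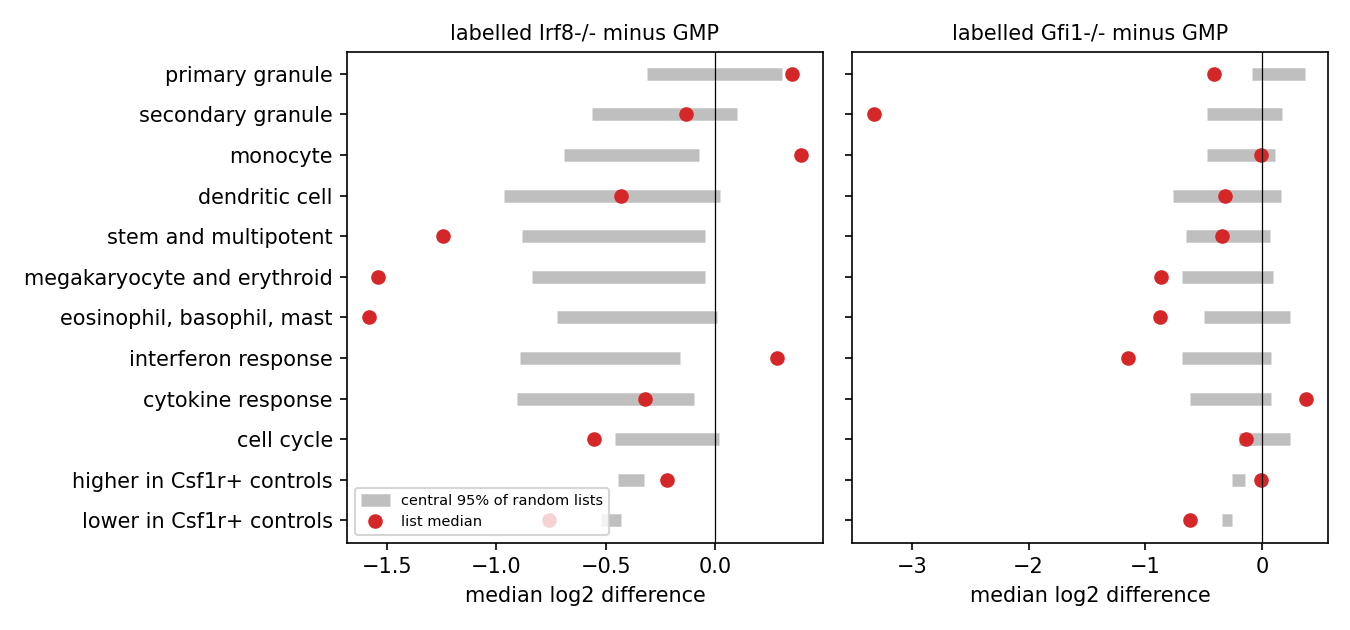
Median log2 difference from GMP of 12 gene lists (red points) in the libraries labelled Irf8-/- (left) and Gfi1-/- (right), with the central 95% of 10000 random lists matched on mean expression (grey bars). The secondary granule median is -0.14 in the library labelled Irf8-/- and -3.32 in the library labelled Gfi1-/-.

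Set directly against each other, the knockout-labelled libraries differed in granule, interferon and some monocyte genes. Of 14 secondary granule genes, 7 were lower and 1 higher in the library labelled Gfi1-/- than in the library labelled Irf8-/- (median -3.00, percentile 0), with Chil3 at 26.7 against 1681 TPM. Ly86 was at 54.7 against 0.22 TPM, Klf4 at 17.2 against 0.14 TPM and the protease Ctss at 128 against 9.39 TPM. The interferon list was lower (median -1.35, percentile 0, 5 of 13 lower) and the stem cell list higher (median 0.95, percentile 99.99, 4 of 13 higher and 1 lower), with Hoxa9 at 41.7 against 2.71 TPM. In total 374 genes were higher and 231 lower, with a median of 0.26, and median-of-ratios scaling gave 229 higher and 336 lower.

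The genes called between the Csf1r gates were then followed in these libraries. Genes lower in Csf1r-positive GMP had a median log2 difference of -0.76 in the library labelled Irf8-/- and -0.62 in the library labelled Gfi1-/-, both at percentile 0 among matched random lists. Genes higher in Csf1r-positive GMP had medians of -0.22 and -0.01, both at percentile 100. With median-of-ratios scaling the medians were -0.34 and -0.40 for the lower genes and 0.20 and 0.23 for the higher ones, at the same percentiles, so the sign of the latter rests on the scaling. Both differences use the same GMP library, so part of their likeness may come from it. Taken directly, the library labelled Gfi1-/- differed from the library labelled Irf8-/- by medians of 0.17 (percentile 0.92) and 0.25 (percentile 70.4) for the lower and higher genes.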

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

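No named gene that was called changed sign under any alternative run, but the larger side of some counts did. It turned between the Csf1r gates after quantile normalization (705 higher, 584 lower) and without Csf1r-negative replicate 1 (637 and 531), and between the knockout-labelled libraries with median-of-ratios scaling (229 higher and 336 lower, against 374 and 231). Of 1596 genes called between the Csf1r gates, 1331 were also called with a pseudocount of 0.1, 1516 with a pseudocount of 5, 994 when every gene above 0 was tested, 1281 with a minimum of 5 TPM, 1089 after quantile normalization, 1336 after median-of-ratios scaling and 1556 with ribosomal and small RNA rows left out, an alternative chosen after seeing the data. Counts that moved by over 1.5 times were 354 genes higher in Csf1r-positive GMP when every gene above 0 was tested and 584 lower after quantile normalization. Leaving out each library gave 518 to 1168 genes in all, 152 to 637 higher and 366 to 703 lower. The lone library of a gate was then assumed to vary like the other gate. Of 95 named genes, 19 lost their call and 14 gained one under at least 1 alternative. The control names differ between the gates and share only the stems CAG and Rosa, and no label pairs them. With these 2 pairs as a replicate block, 3580 genes passed, 1289 higher and 2291 lower, and deviations of libraries with the same stem correlated at 0.357 across genes. All 1596 called genes had the same direction in both pairs, but this adds nothing, since none of them overlapped between the gates and any pairing gives the same. Of the 9 lists called by camera with a preset correlation, 0 held with an estimated one. The estimate rests on 2 residual degrees of freedom, so it cannot decide whether a list differs. Without a Csf1r-negative library fewer genes met the minimum, which accounts for part of the loss among list members. For the other counts the cause was not tested.

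For single libraries, a pseudocount of 5 lowered the counts by construction, to 404 (CMP against LSK), 413 (GMP against LSK), 839 (labelled Irf8-/-) and 442 (labelled Gfi1-/-). Median-of-ratios scaling gave 636 for the library labelled Irf8-/-, since it removes the shift of the median, and a minimum of 20 TPM gave 507 for the library labelled Gfi1-/- because fewer genes were counted. With the CMP library as the reference, 1183 genes met the rule against both references in the library labelled Irf8-/- and 554 in the library labelled Gfi1-/-. No alternative for Gfi1 induction, its interaction or the transgene level was run, nor the Csf1r test in induced libraries alone; control libraries alone are the main test. The depth behind these values is unknown.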

Other observations

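All tests in this part were chosen after the results were seen. The 4 Csf1r-sorted controls were also set beside the unsplit GMP library, a comparison not made above. Csf2rb, the shared receptor chain for interleukin-3 and GM-CSF, was at 791 to 1053 TPM in the sorted controls and 62.6 TPM in GMP. Cish, a feedback gene of STAT5 signalling, was at 40.5 to 62.1 and 1.29 TPM, Socs3 at 16.2 to 17.5 and 0.16 TPM, and Thbs1 at 383 to 600.3 and 0.58 TPM. Some genes that separated the gates most were low in GMP. Gzmb was at 609 and 839 TPM in Csf1r-negative controls and 6.51 TPM in GMP, and Pf4 at 757 and 1016 TPM and 9.19 TPM. Both still lay between the gates, whereas Lyz2, at 557 TPM in GMP, lay below both (648 TPM or more). Of the cytokine response genes, 6 of 16 were higher by at least 1 on the log2 scale in all 4 sorted libraries and 1 lower. The same held for 6 of 15 integrated stress genes (none lower, list median 0.99, percentile 100 among matched random lists) and 5 of 16 glycolysis and hypoxia genes (1 lower, median 0.68, percentile 99.93). Monocyte (median 1.22, 2 of 20 higher and 2 lower) and dendritic cell lists (median 0.93, 3 of 12 higher) lay at percentiles 100 and 99.91. Of 15 secondary granule genes, 7 were lower by this measure and 1 higher (median -2.15). Of 15 primary granule genes, 9 were lower (median -1.62), and of 13 eosinophil, basophil and mast cell genes, 4 were lower (median -1.325), with none higher in either list. These 3 lists lay at percentile 0. The interferon list had a median of -0.89 (percentile 0.03), with 1 of 16 genes lower by this measure.

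The GMP library held mRNAs of more intestinal genes than any other library. Reg3b was at 22.4 TPM, Fabp2 at 10.5 TPM, Reg3g at 5.93 TPM, Tff3 at 3.07 TPM and Fabp1 at 3.02 TPM, and all 5 were listed at 0 in the other 8 libraries. A list of 20 intestinal markers was written after Reg3b and Fabp2 were seen. Of the 18 other than these, 6 reached 1 TPM in GMP, 1 in LSK, 1 in a Csf1r-negative library and none in the other 6. Whether material or index reads of another sample entered the GMP library was not tested, and this library is the reference for both knockout labels and for the sorted controls. H2-Q7 and H2-Q8 were listed at 0 in the library labelled Gfi1-/- and stood at 30.1 and 32.7 TPM in GMP. H2-Q9 was at 0.32 and 31.8 TPM in the same order. H2-Q8 was also listed at 0 in the 4 Csf1r-sorted controls. There H2-Q7 was at 1.18 and 4 TPM in Csf1r-positive and 23.4 and 42.8 TPM in Csf1r-negative GMP. H2-Q9 was at 1.46 and 4.13 TPM in the former and 16.93 and 21.85 TPM in the latter. In CMP, LSK and the library labelled Irf8-/-, these genes were at 17.6 TPM or more. Near-identical copies make each value uncertain, but reads divided differently among these copies alone would not lower all of them. The cause was not tested.

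The CMP and GMP libraries were closer to each other than replicate libraries of a Csf1r gate. Those replicates carry the different stems CAG and Rosa, and small RNA rows took 0.0164 and 0.024% of the CAG libraries and 0.197 and 0.207% of the Rosa ones. The replicate spread may therefore be a wide yardstick. The CMP and GMP values were not copies of 1 library, because the secondary granule list differed by a median of 2.25. That difference cannot exclude the same cells or library with reads of other cells added to the GMP library, which was not tested. Whether the library labelled CMP came from cells of the GMP gate stays open. Fcgr3, whose protein separates the gates, differed by 0.03, but the megakaryocyte and erythroid list had a median of -0.26 (GMP minus CMP, percentile 0), which is small yet in the direction of a CMP library. A real likeness of the 2 populations in these gates stays open, as untested.

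The mRNA of each targeted gene was higher in the library labelled as its knockout. Exchanged labels are argued against by the secondary granule genes, which neutrophils lacking Gfi1 are known to lose: their median in the library labelled Irf8-/- was -0.14, within the central range of matched random lists. Reads from exons that the targeting left in place, together with a loss of self-repression, may account for the rise of Irf8 (log2 difference 1.47) and Gfi1 (0.76), but cannot be told apart from an intact gene because the values are sums per gene.

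For the difference between sorted controls and GMP, a GMP library that is only a mixture of both gates as measured is argued against by 4 of 8 eosinophil, basophil and mast cell genes. Prg2, Epx, Prg3 and Prss34 lay above the highest sorted library by a factor of 2 or more (Prg2 at 2725 against 239 TPM). These 4 are the members already counted as lower in the sorted controls, and LSK also held them (1395, 171, 61.8 and 53.1 TPM). A mixture of the gates together with another difference between the sorted controls and GMP therefore stays open. Ribosomal RNA rows taking part of the total lower all other genes, so they cannot raise the higher lists. They do not account for the lower ones either, since the primary granule median was -1.45 and the interferon median -0.80 once those rows were left out. Overnight culture may raise cytokine response genes (median 1.498 with all rows), but it cannot be told apart from any other difference between the 4 sorted controls and GMP, because the labels do not say which of these cells were cultured. A difference between the mice also stays open, as untested.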
